A study of Danio rerio with 2 samples.

How the data were processed

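Total RNA of zebrafish embryos at 24 hours after fertilization was labelled with biotin and hybridized to Affymetrix zebrafish expression arrays, per the labels. There were 2 arrays, 1 for embryos given a C1q-like morpholino and 1 for embryos given a control morpholino with 5 mismatches, each at about 5 ng per embryo. Groups were taken from the sample descriptions. The number of embryos behind each array is not given in the sources used here.

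The authors deposited 1 signal per probe set and array, computed with MAS5 per the submitters' processing notes. Neither the version of MAS5 nor its scaling target is given in the sources used here. The signals were on a linear scale, from 0.4 to 27084.5 on the C1q-like morpholino array and from 0.2 to 15372 on the control array. The mean without the highest and lowest 2% of values was 98.8 and 99.4, so the arrays had been scaled to nearly the same level. MAS5 subtracts background with mismatch probes and scales each array by 1 factor, which leaves any trend with signal in place. No detection calls were used here. Of 42 scanner and fluidics settings in the deposited experiment files, 2 differed between the arrays, the day of hybridization and the day of scanning.

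Signals were used as the authors scaled them. Each was raised to a floor of 33.3, the median of all signals of both arrays, because low MAS5 signals are mostly background. The log2 ratio of C1q-like morpholino over control morpholino was then taken. Where 1 signal lay below the floor, a fold is a lower bound. Genes were named from the platform annotation, updated through Entrez gene numbers with the RefSeq gene table of assembly GRCz12tu, of which no coordinates were used. Of 15502 probe sets 10795 named 1 gene, 135 several and 4572 none, and 10711 of the first kind were found in the RefSeq table. No gene was read from a probe set naming several, except that the shared globin probe sets were given as such. Each of 8796 genes was read through its probe set with the highest mean log2 signal, and 1539 genes had several. A gene was measured if it reached the floor on at least 1 array, as 5961 did. The symbols dld and dldh were attached to different genes in different annotations and were left out.

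With 1 array per group no test between the groups, p-value or standard error was computed. The bootstrap interval given below was taken over genes and covers spread between genes only. Genes were counted by size, at ratios of at least 2 and 3. There were 34 gene lists, 6 of them the focus (apoptosis, erythroid, blood progenitor, myeloid, endothelial and cell cycle genes), with 905 list names matched to a gene on the array and 420 not. A further list fixed with them is not reported here. Each list was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile, which describes these 2 arrays and not the conditions. Lists with under 5 measured genes were given values only. The lists, the floor, the limits, the alternatives and the rule for naming genes were choices made before the data were examined. That rule took the C1q-domain family, the 12 highest and 12 lowest genes with a proper symbol, the 2 highest and 2 lowest members of each list, and by name mdm2, cdkn1a, gata1a, the embryonic globins, tal1, spi1b, mpx, lyz and kdrl. The added counts of list members past 2-fold were chosen after the data were seen.

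The alternatives were floors at the 25th and 75th percentile or none, centring on the median, quantile normalization, lowess centring (span 0.3), the mean over all probe sets of a gene, leaving out probe sets with shared probes, random lists not matched on signal, and list means. Probe sets were taken to share probes where their identifier ended in _x_at, _s_at or _a_at. The suffix _a_at marks probes shared by transcripts of the same gene, not by different genes. A planned reading of array control probe sets was not made, since none were among the rows used here. The steps were tested on simulated data with 5968 genes, made from the control signals with independent noise of an assumed size. Changed genes were drawn from brighter probe sets only, so the shares below do not cover dim genes near the floor. Simulated genes varied independently, so the list results do not cover lists whose genes vary together. Of genes simulated 2-fold higher 97.9% had the right sign and 51.1% were at least 2-fold higher, and of those 2-fold lower 97.7% and 41.9%. At 4-fold, 97.8% and 85% passed 2-fold. Of 400 random lists of 25 genes 4% fell outside the limits, and of 100 lists lowered by 0.5 on the log2 scale 92% were found. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.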

Results

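The series held 2 expression arrays of zebrafish embryos collected at 24 hours after fertilization. A morpholino is a synthetic antisense oligomer that blocks translation or splicing of a chosen transcript. Embryos of the first group had received a morpholino against a C1q-like gene, whose protein resembles the C1q component of complement. Embryos of the second had received a control morpholino carrying 5 mismatches to the same target, and both groups were given about 5 ng per embryo. Each group was represented by 1 array, so no difference below has a replicate check and no test between the groups was possible. Values are signals of the C1q-like morpholino array set against the control morpholino array, and "higher" or "lower" describes these 2 arrays. The arrays were hybridized and scanned on different days, 1 array per day, so day and group cannot be told apart in any value. The purpose given for the series was to find which genes and pathways depend on the C1q-like gene.

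Each array gave a signal for 15502 probe sets, with a median of 34.7 on the C1q-like morpholino array and 32.0 on the control array. Signals below 33.3, the median over both arrays, were raised to that floor before any ratio was taken. On the C1q-like morpholino array 7934 probe sets (51.2%) lay at or above the floor, and on the control array 7590 (49.0%). The arrays ranked the probe sets alike, with a Spearman rho of 0.899 across probe sets, which are not independent replicates. Their number, 1 per group, limits the precision.

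The knocked-down gene could not be checked by name, because no probe set used here carried it. Genes of the C1q-domain family with symbols starting in c1q or cbln were read in its place, and all 6 were near or below the floor. The complement gene c1qc had signals of 42.5 with the C1q-like morpholino and 14.3 with the control. The precerebellin relative cbln11 read 49.3 against 17.7, and c1qtnf5 read 39.4 against 27.5. Both signals lay below the floor for c1ql3b, cbln1 and c1qtnf4. The median log2 ratio of the 3 measured members was 0.35, a lower bound because their control signals all lay below the floor. These values do not check the labels, since no probe set used here was named for the target. Even for the target, a morpholino that blocks translation need not alter its RNA.

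The highest named gene was phlda3, encoding an inhibitor of Akt, at 6.31-fold higher with the C1q-like morpholino (210.1 against 33.3, a control signal equal to the floor). With the higher floor its log2 ratio of 2.66 was 1.17. The ribosomal protein S27-like gene rps27l was 6.30-fold higher (2630.1 against 417.7), and the cyclin G gene ccng1 was 4.19-fold higher (6768.9 against 1615). The ubiquitin ligase gene mdm2 was 3.02-fold higher (298.4 against 98.9). The gene cdkn1a was not analysed here.

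Genes of the apoptosis machinery went both ways. Of 22 measured, 10 had ratios above and 12 below 1, and the median log2 ratio was -0.04 (34.6th percentile). The pro-apoptotic gene baxa was 2.62-fold higher, with signals of 344.3 and 131.2, and diabloa, encoding a mitochondrial inhibitor of caspase inhibitors, was 2.22-fold higher. The control signal of diabloa lay below the floor, so that ratio is a lower bound. The caspase inhibitor gene birc2 had a log2 ratio of -1.05 and the BH3-only gene bida -0.96.

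**Figure D1:**
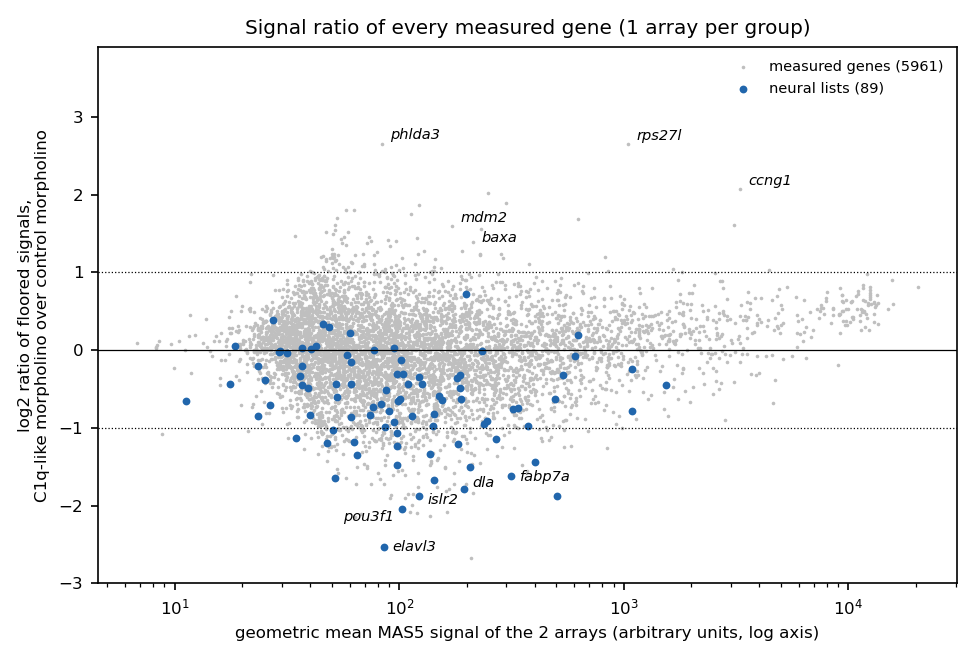
Log2 ratio of the floored signals, C1q-like morpholino over control morpholino, against the geometric mean signal of the 2 arrays in arbitrary units on a log axis. Grey points are the 5961 measured genes and blue points 89 genes of 3 neural lists. Dotted lines mark 2-fold differences; phlda3 and rps27l stand highest, and most blue points lie below 0.

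Genes of the nervous system were lower with the C1q-like morpholino. Of 38 measured neural progenitor genes 35 had ratios below 1, and 12 were at least 2-fold lower against 1.57 in matched random lists. The POU factor gene pou3f1 was 4.11-fold lower and fabp7a, encoding a lipid-binding protein of radial glia, was 3.08-fold lower, whereas her6 and sox19b had log2 ratios of 0.19 and 0.34. Of 33 neuron genes 28 were below 1 and 8 were at least 2-fold lower. They were led by elavl3, the pan-neuronal RNA-binding protein also called HuC, at 5.77-fold lower (35.5 against 204.7), and by islr2 at 3.67-fold lower. A dimmer probe set of elavl3 had a log2 ratio of 0.58 in the opposite direction. The log2 ratio of elavl3 was -2.53, against -0.97 as a mean over its probe sets and -1.14 with the higher floor. The neuron genes dlx5a and gad1b lay above 1, at log2 ratios of 0.72 and 0.30. The median log2 ratios were -0.75 for neural progenitor genes and -0.59 for neuron genes, each below all 10000 random lists. The 19 brain regional identity genes had a median of -0.44 (0.16th percentile). Among them otx2b, a forebrain and midbrain homeobox gene, had signals of 25.7 against 104.2 and pax6a had a log2 ratio of -1.07, while fgf8a was at 0.39 and six3b at 0.22. The brain regional call was lost with a higher floor, at -0.26 over 8 genes. The 13 eye and lens genes had a median of -0.48 (0.04th percentile), with 5 at least 2-fold lower. These included sox11b at -1.15 and the lens crystallin gene crygmxl2 at -1.13, with rpe65a at 0.23 and exorh at 0.13 above 0. Some genes belong to several of these lists, and the neural progenitor, neuron and brain lists together held 89 different measured genes.

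Cell cycle genes were also lower, by a smaller amount. Of 63 measured, 50 had ratios below 1, and the median log2 ratio was -0.38, below all 10000 random lists. At least 2-fold lower were 7 genes, against 2.38 in random lists. The condensin genes smc2 and smc4, needed to compact mitotic chromosomes, had log2 ratios of -1.58 and -1.32. The replication factor gene rfc5 and the histone variant gene h2az2b were above 1, at 0.70 and 0.69.

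**Figure D2:**
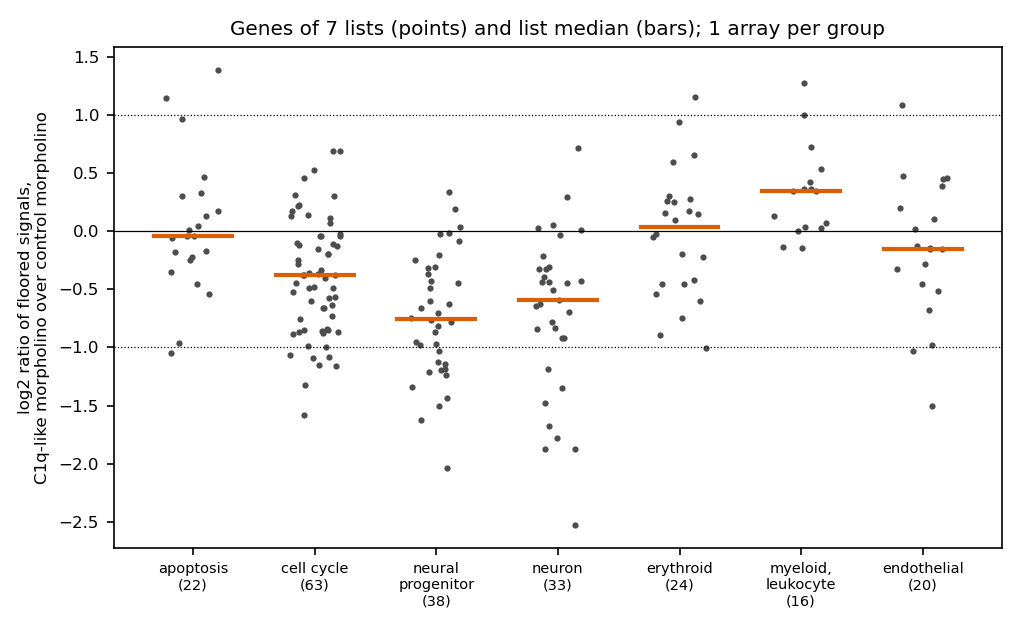
Log2 ratio of the floored signals, C1q-like morpholino over control morpholino, for each measured gene of 7 lists (points, spread sideways at random) with the list median (orange bars); each group is 1 array and the numbers in parentheses count genes. The medians of the neural progenitor list (-0.75), the neuron list (-0.59) and the cell cycle list (-0.38) lie below 0.

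Blood was examined because the study was known to be concerned with blood formation. The 24 measured erythroid genes were evenly divided, 12 above and 12 below a ratio of 1, with a median log2 ratio of 0.04 (51.3rd percentile). The erythroid master regulator gata1a was 2.23-fold higher (77.7 against 34.8, a control signal just above the floor). The heme synthesis enzyme gene alad had a log2 ratio of 0.94. The red cell anion exchanger gene slc4a1a had a log2 ratio of -1.01 and uros, also of heme synthesis, -0.89. The embryonic globins were bright on both arrays. The gene hbae3 read 15610.7 against 9913.6, hbbe3 7208.7 against 5850.5, and hbbe2 735.4 against 662.6. The ratio of hbae3 was 1.57, and a second probe set, which shares probes (_s_at), gave the same log2 ratio of 0.66. A bright probe set shared by the hbbe1 genes was 1.60-fold higher, and the 2 shared by the hbae1 genes were 1.60-fold and 1.08-fold higher. The brightest octile of probe sets had a median log2 ratio of 0.17. The log2 ratio of hbae3 was 0.02 after quantile normalization and 0.10 after lowess centring, and that of hbbe3, 0.30 as deposited, was -0.04 and -0.14.

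The 17 blood progenitor regulators had a median log2 ratio of -0.05 (27.4th percentile), with 8 above and 9 below a ratio of 1. Besides gata1a, drl was at 0.95, while sfpq was at -1.03 and pbx1a at -0.85. The stem cell leukemia gene tal1 lay below the floor on both arrays, at 1.2 and 8.3. Myeloid and leukocyte genes were higher as a group. Of 16 measured, 13 had ratios above 1 and 2 below, and their median log2 ratio of 0.35 lay at the 99.8th percentile. The neutrophil peroxidase gene mpx was 2.42-fold higher (201.3 against 83.2), although its 3 other probe sets were below the floor. The cathepsin gene ctss2.1 read 977.3 against 489.1. The log2 ratio was -0.13 for lyz, encoding lysozyme, and -0.14 for lcp1. The myeloid regulator spi1b read 43 against 23.5. With the lower floor or none the myeloid median was 0.28 and lay within the limits, at the 90.7th and 79.3rd percentiles. The 20 endothelial and vascular genes had a median of -0.15 (9.05th percentile). Their lowest members were cdh2, a cadherin also listed for heart and neural progenitors, at -1.50 and notch3, also listed for neural progenitors, at -1.03. The vascular receptor gene kdrl was at -0.68, with dim signals (33.3 against 53.3, the first equal to the floor). The gene aqp8a.1 was at 1.09 and fli1rs at 0.48. With the lower floor or none the endothelial median was -0.30 or -0.37, outside the limits.

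Of the remaining tissues, epidermis and hatching gland stood apart. Of its 35 measured genes 27 had ratios above 1, and the median log2 ratio of 0.39 lay at the 99.8th percentile. The S100 gene icn2 was 2.05-fold higher and the keratin gene krt97 read 2576.5 against 1285.5, while dspa, encoding desmoplakin, was at -0.52 and cldnb at -0.32. Endoderm, liver, pancreas and yolk genes had a median of 0.29 over 32 genes (96.2nd percentile), which was 0.12 after quantile normalization, 0.08 after lowess centring and 0.14 as a mean. Their highest member, fetub, was 2.06-fold higher, followed by gata6 at 0.86. Lowest were neurod1, also listed for neurons, at -1.35 and vtnb at -0.76. Skeletal muscle genes were within the limits, with a median of 0.11 over 35 genes (10.4th percentile). Their extremes were cacng1a at 0.61, myod1 at 0.57, tnnt3b at -0.47 and pvalb3 at -0.45. The heart list had a median of 0.03 over 13 genes (61.2nd percentile), with the cardiac myosin light chain gene myl7 at 0.59 and tbx2b at -0.68. The notochord, floor plate and hedgehog list had a median of -0.13 over 22 genes (9.90th percentile), with ntn1a at -0.99, hhip at -0.86, tbxta at 0.42 and lamb1a at 0.35. The neural crest and pigment list had a median of -0.12 over 19 genes (18.1st percentile). Its lowest member was zeb2a, a zinc finger repressor gene, at -1.72, with sox9b at -0.90, gart at 0.57 and snai1a at 0.65. The 8 pronephros genes had a median of 0.10 (76.0th percentile), between gata3 at -0.54 and jag2b at -0.52 and atp1a1a.4 at 0.64 and slc26a1 at 0.36.

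Segmentation clock and tailbud genes had a median log2 ratio of -0.28 over 14 genes, at the 2.38th percentile, just outside the limits. The Notch ligand gene dla, also listed for neurons, was 3.44-fold lower and hes6 2.13-fold lower. The ventral homeobox gene vox was 3.64-fold higher and aldh1a2 was at 0.43. Without the genes of the neural lists the median was -0.23 over 11 genes (10.3rd percentile), inside the limits. The direction of the full list was not stable. Its median was 0.18 with the lower floor, 0.42 with none and 0.06 without probe sets that share probes. The 32 hox genes had a median of -0.10 (17.8th percentile), ranging from hoxb8a at -1.13 and hoxc8a at -0.84 to hoxa9a at 0.74 and hoxb10a at 0.71. The Wnt, Bmp, Fgf and Notch feedback genes had a median of -0.11 over 33 genes (16.0th percentile). The Notch ligand gene dlb, also listed for neurons, was 3.19-fold lower, and spry2 and bmp2b were at 0.60 and 0.58. This list lay outside the limits with the lower floor or none, at -0.21, and as a mean, at -0.23.

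**Figure D3:**
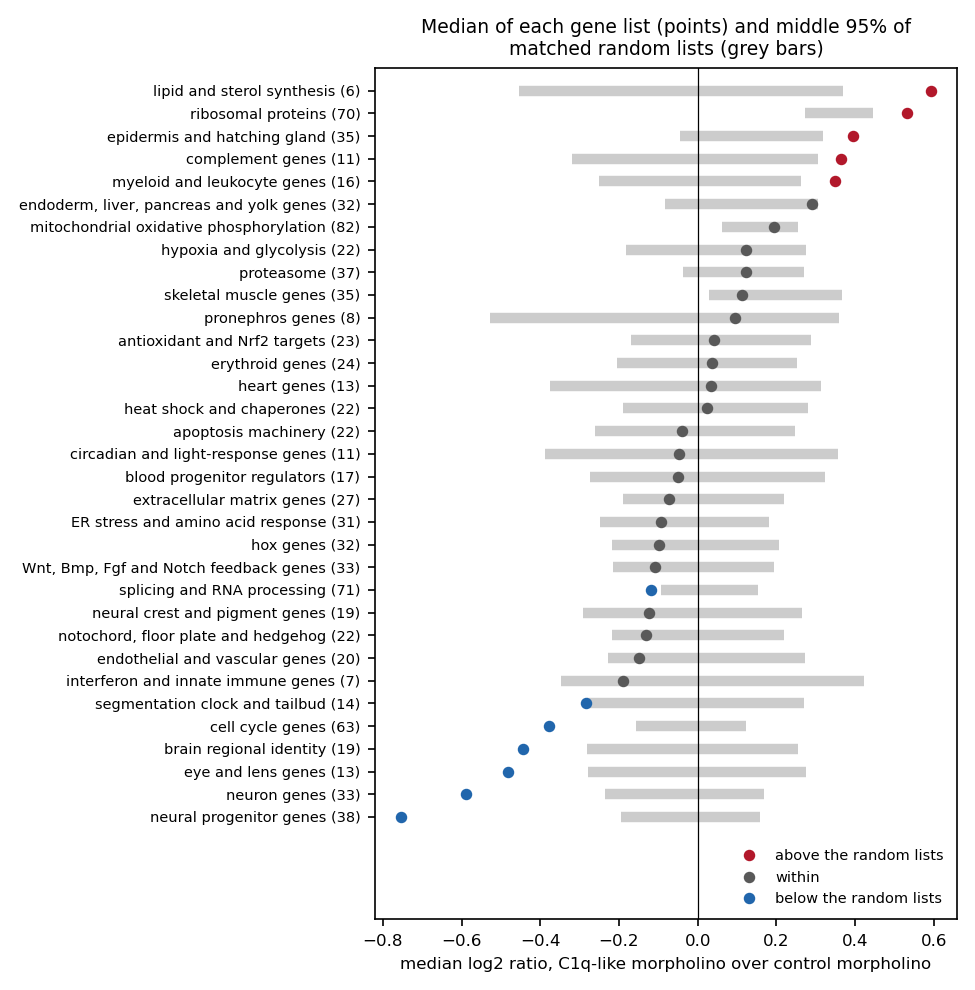
Median log2 ratio, C1q-like morpholino over control morpholino, of 33 gene lists (points, measured genes in parentheses) with the middle 95% of the medians of 10000 random lists matched on signal (grey bars). Red points lie above and blue points below the bars; the lowest are neural progenitor genes (-0.75) and neuron genes (-0.59).

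Across all 5961 measured genes, 101 (1.69%) were at least 2-fold higher with the C1q-like morpholino and 244 (4.09%) at least 2-fold lower. At 3-fold the counts were 14 and 36. The lower genes made up 70.7% of those past 2-fold, against 57.4% after quantile normalization and 60.5% after lowess centring. The excess of lower genes depended on the floor. Higher genes outnumbered lower ones with the floor at the 25th percentile, 547 against 449, and with none, 1118 against 893. Of the 33 lists with at least 5 measured genes, 5 lay above and 7 below the limits. If the lists were independent random sets of genes, 1.65 would be outside. Lists share genes and the genes of a list may vary together, so that number does not measure chance for these lists.

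The 12 highest named genes included, besides phlda3, rps27l, ccng1 and vox, the exonuclease gene isg20 at 4.06-fold, ctsc, encoding cathepsin C, at 3.73-fold, and the RNA polymerase III subunit gene polr3f at 3.49-fold. The growth factor gene igf2a was 3.38-fold and bzw1a 3.05-fold higher. The follistatin gene fsta was at least 3.49-fold and gpr137 at least 3.25-fold higher, as their control signals were below the floor. The claudin gene cldng was 3.21-fold higher by its brightest probe set, whose probes are shared by transcripts of the same gene (_a_at). Its 2 other measured probe sets gave log2 ratios of 0.22 and -0.01, and the one at -0.01 also shares probes (_x_at). For cldng the log2 ratio was 1.66 after lowess centring and 0.0016 after quantile normalization. The brightest probe set was picked anew under each setting. The quantile value lies close to the -0.01 of a probe set almost as bright, so it may reflect a switch of probe set. The lowest gene with a proper symbol was hsp70.3, an inducible heat shock gene, at 6.40-fold lower (82.1 against 525.8) by a probe set that shares probes. Among the 12 lowest were also genes of neurons, namely elavl3, islr2, otpb, a homeobox gene of hypothalamic neurons, at 4.22-fold lower, and gpm6aa, a neuronal membrane glycoprotein gene, at 3.99-fold lower. The amyloid precursor gene appa was 4.27-fold lower by a probe set whose probes are shared by transcripts of the same gene (_a_at). A dimmer one of the same kind gave a log2 ratio of -0.82. The coactivator gene crebbpb was at least 4.29-fold lower, the splicing kinase gene clk4a 4.23-fold lower and polr2a, encoding the largest subunit of RNA polymerase II, 3.75-fold lower. A second probe set of polr2a gave -1.63. The gene acin1a was at least 4.41-fold lower, and its other measured probe set read 16.7 against 35.8, near the floor, while ppt2a.2 was 3.73-fold lower.

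Probe sets of 1 gene gave a view of measurement error, though not of variation between embryos. Over 789 genes with several measured probe sets, the log2 ratios of a pair had a Pearson r of 0.389 and a Spearman rho of 0.382 across genes. Of 71 genes at least 2-fold apart by the brighter probe set, 56 (78.9%) had the same sign by the other and 15 were also 2-fold apart. Where both probe sets were above the 75th percentile of signals, r was 0.596 and 21 of 23 had the same sign.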

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

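The tests on scaling were chosen before their results were seen; those on developmental delay, cell share and day were chosen after. Probe sets without a gene name were outside the gene and list comparisons, and the 2 with the highest ratios among them are given here. The first, DrAffx.1.85.A1_at, had a signal of 1360.1 with the C1q-like morpholino and 139.1 with the control, 9.78-fold higher. Its identifier shares a stem with that of the probe set for the hbbe1 globins, which read 18336.3 and 11493.4. The other read 1316 and 321.6, 4.09-fold higher. The lowest probe sets without a name read 43.5 against 412.3 and 129.8 against 1010.3. Of 1656 measured probe sets without a name 34 were at least 2-fold higher and 112 at least 2-fold lower.

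The lower signals of neural genes spanned 3 lists, with a median log2 ratio of -0.63 over 89 genes. Of these, 21 were at least 2-fold lower, against 3.96 in random lists. A trend with signal between the arrays was argued against, since the median was -0.52 after lowess centring, below all random lists. A general delay of development stayed open: tailbud genes outside the neural lists lay at the 10.3rd percentile and skeletal muscle genes at the 10.4th, and no series of stages was used here. A smaller share of neural cells also stayed open. The spread of the shifts of 9 lists of other cell types lay at the 89.4th percentile of that of random lists, and this test replaced an earlier one after its result was seen. The earlier one set epidermis against notochord, a pair picked from their medians, and gave a difference of 0.43. Its 95% bootstrap interval, 0.05 to 0.77, covers spread between genes only, not between embryos or arrays. It would have argued against that explanation, but a pair picked in this way cannot decide it. With 1 array per hybridization day, day cannot be told apart from morpholino either.

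Ribosomal protein genes were higher by a median log2 ratio of 0.53 over 70 genes, above all random lists, whose middle was 0.37. These genes are among the brightest on the array. After lowess centring the median was 0.014, within the limits, so the difference may come from scaling that depends on signal. Centring removes any shift that bright genes share, whether from scaling or from the embryos, so it cannot tell these apart.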

How the results depend on the processing

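The ribosomal list without rps27l was chosen after the data were seen, and the other alternatives were planned. Of 327 comparisons of a list with an alternative, 299 kept their side of the limits, 8 moved outside and 16 moved inside with the same sign. In 4 more a list that stood apart moved inside with its sign turned, and no list stood apart in the opposite direction. In 28 of the 299 the median of a list inside the limits also turned sign. These came from 11 lists, of which 6 turned under another scaling (erythroid, blood progenitor, heat shock, ER stress, skeletal muscle and extracellular matrix genes). The interferon list turned to 0.09 with the lower floor, 0.51 with none and 0.23 as a mean, so such medians carry no direction. The side of the limits held for 22 lists under every alternative run on them, among them neural progenitor (-0.76 to -0.66), neuron (-0.71 to -0.44), cell cycle (-0.40 to -0.34), epidermis (0.28 to 0.54) and eye and lens genes (-0.60 to -0.46). Of 280 comparisons of 36 named genes 250 stayed close and 30 moved. With the higher floor the log2 ratio of phlda3 went from 2.66 to 1.17, elavl3 from -2.53 to -1.14, pou3f1 from -2.04 to -1.16, fsta from 1.80 to 0.32, polr3f from 1.80 to 0.33 and gpr137 from 1.70 to 0.22.

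Genes at least 2-fold higher numbered 547 with the floor at the 25th percentile, 31 at the 75th and 1118 with none, and those lower 449, 103 and 893, so lower genes were no longer in excess with the lower floor or none. At 3-fold the counts were 74, 7 and 560 higher and 78, 12 and 410 lower, and 23 lower with the mean over all probe sets. A lower floor lets more dim genes in, by construction. Of the 12 highest and 12 lowest genes, 5 and 4 were kept with the lower floor, 7 and 2 with the higher, and 0 and 0 with no floor. Ranking by the ratio over the local spread kept 9 and 5, and lowess centring 10 and 11.

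With the lower floor and with none, medians were 0.28 and 0.28 for myeloid genes and 0.36 and 0.45 for complement genes (0.16 with the higher floor), all inside the limits. Endothelial genes lay outside at -0.30 and -0.37, and Wnt, Bmp, Fgf and Notch feedback genes at -0.21 and -0.21 (-0.23 as a mean). Lipid and sterol genes were inside at 0.52 with no floor, and brain regional genes at -0.26 with the higher floor. The segmentation and tailbud list turned sign inside the limits, to 0.18 with the lower floor, 0.42 with none and 0.064 without shared probes. It was also inside at -0.48 with the higher floor, -0.21 after quantile normalization, -0.23 after lowess centring, -0.17 over all probe sets, -0.28 against unmatched lists and -0.18 as a mean. Ribosomal proteins were inside at -0.030 after quantile normalization and 0.014 after lowess centring. Splicing genes were inside at -0.10 after lowess centring and -0.12 against unmatched lists. Unmatched lists put endoderm genes (0.29) and oxidative phosphorylation genes (0.19) outside, as did leaving out shared probes for endoderm genes (0.31), whereas lowess centring gave 0.08 and 0.05, inside the limits. Except for the counts under other floors, the cause was not tested. Probe set agreement was r = 0.596 for bright probe sets. No paired analysis was possible because each group holds 1 array. Signals near the floor limit what can be read of dim genes.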

Other observations

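Complement genes had a median log2 ratio of 0.36 over 11 genes (99.0th percentile), with the complement gene c8g at 0.89, c3a.1 at 0.62, c9 at -0.57 and cfhl4 at -0.03; the list was within the limits at each other floor. The 6 measured lipid and sterol synthesis genes all had ratios above 1, with a median of 0.59 (99.9th percentile), led by aclya at 0.82 and fdps, of the mevalonate pathway, at 0.71, with dhcr7 at 0.21 and elovl5 at 0.03. With no floor the lipid median was 0.52, inside the limits at the 91.4th percentile. Splicing and RNA processing genes had a median of -0.12 over 71 genes (0.75th percentile). It was inside the limits after lowess centring (2.61st percentile) and against unmatched lists (4.24th). The splicing factor gene srsf6b was 2.39-fold lower and lsm14ab was at -1.12, while prpf38a was at 1.01 and sf3b5 at 0.72. Besides rps27l, the ribosomal protein genes ran from rps3 at -0.20 and rpl27a at 0.11 to rpl8 at 0.91.

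The heat shock and chaperone list had a median of 0.02 over 22 genes (38.8th percentile). The list held none of the inducible hsp70 genes named for it, as these were not matched. The lowest gene with a proper symbol, hsp70.3, is not a member. The small heat shock gene hspb1 was 2.30-fold higher and hspbp1 was at 1.05, while the co-chaperone genes dnajb1b and dnaja2b were at -1.47 and -0.99. The ER stress and amino acid response list had a median of -0.09 over 31 genes (27.1st percentile), in which chac1 was 2.82-fold and atf4b 2.74-fold lower, and gadd45aa was at 0.90 and atf3 at 0.56. Antioxidant and Nrf2 target genes had a median of 0.04 over 23 genes (41.9th percentile), with sqstm1 at 1.23, osgn1 at 0.72, nfe2l2a at -0.72 and sod2 at -0.77. Hypoxia and glycolysis genes had a median of 0.12 over 22 genes (71.5th percentile), from hif1ab at -0.88 and pgk1 at -0.66 to eno1a at 0.65 and ldhba at 0.51. The 7 interferon and innate immune genes had a median of -0.19 (12.1st percentile), a direction that turned to 0.09 with the lower floor, 0.51 with none and 0.23 as a mean. Among them isg15, an interferon-induced ubiquitin-like gene, read 92 against 12.9, and irak4 was at 0.75, nfkbiab at -0.24 and socs3a at -0.26.

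Among the housekeeping lists, mitochondrial oxidative phosphorylation genes had a median of 0.19 over 82 genes (79.2nd percentile), which was 0.08 after quantile normalization and 0.05 after lowess centring, with sdhaf2 at 0.97, ndufaf4 at 0.62, ndufa12 at -0.49 and atp5mj at -0.58. Proteasome genes had a median of 0.12 over 37 genes (46.6th percentile), with psma5 at 0.58, psmd5 at 0.51, psmb10 at -0.24 and psmd11b at -0.76. Extracellular matrix genes had a median of -0.07 over 27 genes (17.3rd percentile), with the collagen genes col1a2 at -0.90 and col5a2a at -0.80 and with mmp2 at 0.91 and itga5 at 0.53. The 11 circadian and light-response genes had a median of -0.05 (44.1st percentile), with nfil3-5 at -1.55, per2 at -0.99, cry5 at 0.18 and cry1a at 0.82.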
